A study of Homo sapiens with 27 samples.

How the data were processed

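RNA sequencing libraries were made from human lung fibroblasts, the matrix-producing cells of the lung connective tissue. There were 3 fibroblast samples named N1, PF2 and PF3, called lines here. Per the labels, N1 is a normal line and PF2 and PF3 are pulmonary fibrosis lines. Cells were plated at 200K per well and kept overnight in serum-free DMEM. The serum-free group was given no serum. The other wells were then given 20% fetal bovine serum (FBS), alone or with 1 mM pirfenidone, for 24 hours. Pirfenidone is an oral antifibrotic drug. The hours of the serum-free group after the overnight period are not given in the sources used here. If they were fewer, time in culture cannot be told apart from serum. Each line and treatment has 3 libraries, which makes 9 groups and 27 libraries. They are called wells below. The labels do not say that the 3 come from separate cultures, nor that the 3 lines come from separate donors, so p-values between wells measure only the spread between these samples, which may be technical.

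Per the labels' protocols, RNA was isolated with a column kit with DNase digestion on the column and made into libraries with a stranded total RNA kit. The deposited files hold whole-number read counts per gene, not normalized, with 1 column per library, and the file of each library was equal in every value to its column of the series table in 27 of 27 cases. The number of columns of that table left unused was 0. The genome build is GRCh38 per the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here, so counts of overlapping or antisense genes and of near-identical copies are uncertain. Of 58302 gene identifiers, 58039 matched the GENCODE 29 annotation of GRCh38, and the rest held 0.0115% of all counts. Current symbols were found for 57532 identifiers. Genes of chromosome Y, XIST and TSIX (519 identifiers) were left out of every test for privacy.

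Total counts ran from 20.9 M to 40.6 M reads per library with a median of 24.7 M. At this depth the spread between wells exceeded counting error when averaged over genes, a mean in which abundant genes weigh most. For genes with low counts taken alone this was not tested. For each of the 27 pairs of wells within a group, the mean squared difference over that expected from sampling was between 3.32 and 60.4, and 0 pairs lay at sampling noise. Repeat preparations of 1 culture could exceed it too, so this does not tell whether the wells are separate cultures. In the fits within lines every library was entered as its own sample. CPM, counts scaled to the library total, were computed from the deposited counts with TMM scaling factors, which lay between 0.955 and 1.06 (TMM is edgeR's trimmed mean normalization).

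The treatment comparisons at the line level used the counts of the 3 wells summed for each line and treatment, which gave 9 summed libraries. These were fitted together with edgeR 4.0.16 in R 4.3.3, with filterByExpr at its default minimum count of 10, TMM factors, a term for treatment and a term for line, and the quasi-likelihood F test, on 19706 genes with 4 residual degrees of freedom. The line is what pairs the treatments, since every treatment was given to the same 3 lines. Replicate numbers of wells were given in accession order and pair nothing. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and adjusted p under 0.05 was called a change. Standard errors (SE) of log2 fold changes were derived from the fold change and its F value, with n = 3 lines. Within each line, treatments were compared in 1 fit of all 27 libraries with 9 group means, 17985 genes and 18 residual degrees of freedom. A test with 2 degrees of freedom in that fit asked whether the effect of a treatment differed between the 3 lines. With 1 normal line and 2 fibrosis lines, disease state cannot be separated from the line, and no test of disease was made.

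44 gene lists were written before the data were examined, and 1209 of their 1212 entries matched an identifier. Lists were tested with camera of limma 3.58.1 on the line-level fit with a preset correlation between genes of 0.01, and again with a correlation estimated from the residuals of each list, with adjustment over the 44 lists of a comparison. Genes to be named were also fixed before the data were examined. For serum and for pirfenidone they were the 15 largest rises and the 15 largest falls among protein-coding genes past the threshold with a mean log2 CPM of at least 1 and the same sign in the 3 lines, up to 4 members of each list with the smallest p, 25 fixed genes, and the 10 protein-coding genes with the smallest p for a difference of the pirfenidone effect between lines. Some genes that this rule names are not reported here. Names outside it are marked in the text as chosen after their values were seen.

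The relation between the serum and the pirfenidone effect across genes was computed on log2 CPM with a prior count of 2. Both effects use the wells with FBS, with opposite signs, so the wells were split in all 54 ways that give each effect its own wells in every line. Unchanged groups, with no effect of serum or pirfenidone, were simulated 20 times to give the values that shared wells alone produce in that case.

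The fits were tested on simulated counts with 200 changed genes. Only wells with FBS and with FBS and pirfenidone were simulated. The serum-free wells, which share the spread in the reported fits, were absent, so these rates need not hold for those fits. For pirfenidone at the line level, 18602 genes were tested, 74% of changes of 0.5 and 100% of changes of 1 on the log2 scale were recovered, and 6.45% of the 186 calls were false. For pirfenidone within N1, 16908 genes were tested, 67% and 90% of such changes were recovered, and 5.99% of the 167 calls were false. With no difference between lines simulated, 0 genes were called as differing, in counts whose spread between wells followed expression level alone.

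Alternatives tried were DESeq2 size factors in the edgeR fit, no filter on low counts, DESeq2 1.42.0 in place of edgeR, the 27 wells as replicates, a fit without the line term, only the libraries of the treatments compared, removal of mitochondrial and structural RNA genes, a separate fit for each line, and leaving out each line or well in turn. After the data were seen, PF2 and PF3 were also summed as 1 line, PF3 serum-free wells 2 and 3 were left out, and lists were tested over wells with an estimated correlation. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.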

Results

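Gene expression was measured by RNA sequencing in 3 human lung fibroblast lines, N1 (normal), PF2 and PF3 (both pulmonary fibrosis), in 3 states: kept in serum-free medium, given 20% FBS for 24 hours, or given 20% FBS with 1 mM pirfenidone for 24 hours. Serum holds growth factors and lipoproteins that bring starved fibroblasts back into the cell cycle, and pirfenidone is an antifibrotic drug. Each line and state had 3 wells, giving 27 libraries with total counts between 20.9 M and 40.6 M reads. The design asks what serum changes, what pirfenidone changes in the presence of serum, and whether the lines respond alike. Comparisons with the serum-free wells may also hold a difference in hours of culture, since the hours of those wells are not given. Log2 fold changes below are from edgeR's quasi-likelihood test over the 3 lines unless a line is named, and "rose" or "fell" is used of genes with an adjusted p under 0.05. Levels are CPM as mean ± SD of the line means (n = 3 lines).

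The most similar library of each well came from the same treatment in 27 of 27 cases and from the same line and treatment in 21. The first principal component of log2 CPM held 57.6% of the variance and parted serum-free wells from wells with serum. The second held 9.35% and parted N1 from PF2 and PF3, and the third held 7.89% and parted wells with and without pirfenidone. PF3 serum-free wells 2 and 3 stood apart on the fourth component (3.78%), at 47.1 and 41.8 against 1.84 for PF3 serum-free well 1. In these wells, chosen after their values were seen, CXCL8 was at 434.5 and 250.8 CPM against 102.3 in well 1, MMP1 at 4664 and 2945 against 1208, and COL1A1 at 2596 and 2927 against 6714. Mitochondrial transcripts held 3.03% and 3.29% of their counts against 1.85% in well 1.

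**Figure D1:**
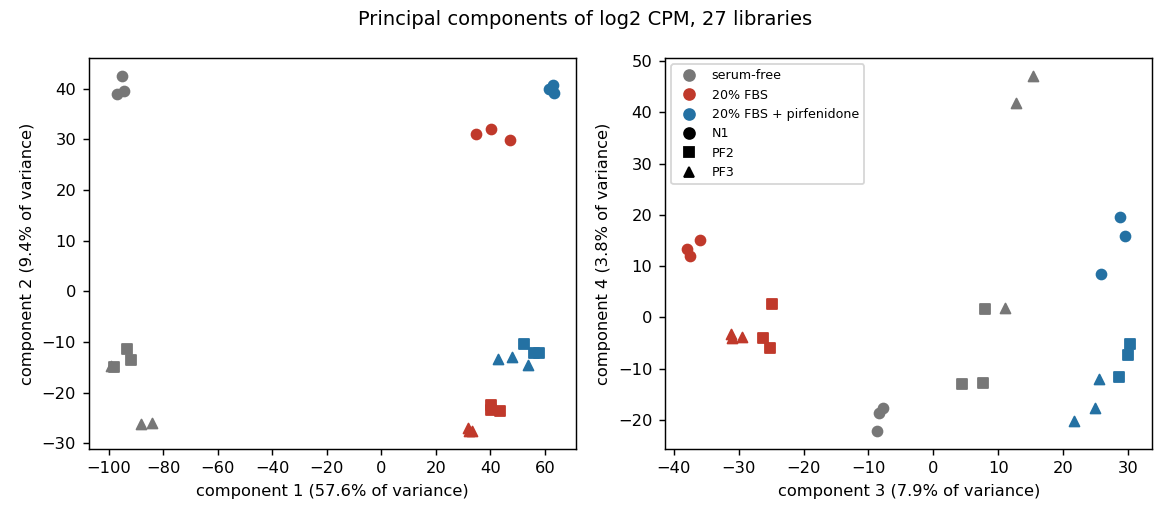
Principal components 1 against 2 (left) and 3 against 4 (right) of log2 CPM for the 27 libraries, with the percent of variance on each axis, treatment shown by colour and line by marker shape. Component 1 (57.6%) separates serum-free wells from the others, component 3 (7.89%) separates wells with pirfenidone from wells with FBS alone, and 2 PF3 serum-free wells lie at the top of component 4, at 47.1 and 41.8.

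With serum, the proliferation marker MKI67 and the myofibroblast actin ACTA2 rose, and the lipofibroblast gene ADH1B fell. MKI67 (ENSG00000148773, GRCh38 chromosome 10, 128096659 to 128126385), went from 33.5 ± 1.48 to 580.3 ± 71.8 CPM, a log2 fold change of 4.12 (SE 0.078, adjusted p = 1.31e-07). ADH1B, an alcohol dehydrogenase (ENSG00000196616, chromosome 4, 99304964 to 99352760), fell from 392.9 ± 277.8 to 2.36 ± 2.17 CPM, a change of -7.44 (SE 0.314, adjusted p = 1.05e-06). ACTA2, the smooth muscle actin (ENSG00000107796, chromosome 10, 88935074 to 88991339), rose from 92.9 ± 34.1 to 649.5 ± 213.4 CPM, by 2.82 (SE 0.377, adjusted p = 0.000368). Of 19706 genes tested, 5871 rose and 6145 fell, 2001 and 2770 of them by at least 2-fold.

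Among the largest rises were ACTC1, the cardiac actin (6.94, SE 0.681, adjusted p = 6.84e-05), the macrophage elastase MMP12 (5.25, SE 0.473, adjusted p = 4.35e-05) and ELN, which encodes elastin (4.94, SE 0.81, adjusted p = 0.00109). Others were NEFM, a neurofilament (4.59), KRT7, a keratin (4.57), ID1 and ID3, inhibitors of basic helix-loop-helix factors (4.58 and 4.49), and the mitotic genes CDC20 (4.85), PLK1 (4.57), CDCA8 (4.53), KIF18B (4.44), DEPDC1 (4.36), UBE2C (4.35), CCNA2 (4.33) and ERCC6L (4.32). The largest falls after ADH1B were the eosinophil chemokine CCL11 (-7.19, SE 0.36, adjusted p = 2.37e-06), the flavin monooxygenase FMO2 (-6.89), LCNL1 (-6.36), the immediate early factors EGR2 (-6.28) and EGR3 (-4.96), RASL12 (-5.90), the bile acid transporter subunit SLC51B (-5.65), FER1L6 (-5.19), the ganglioside synthase ST8SIA1 (-5.18), ADCY8 (-4.93), PPL (-4.89), the fatty acid binding protein FABP3 (-4.87), the sodium channel SCN7A (-4.80) and the monocyte chemokine CCL7 (-4.67).

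Of the lists for growth, those of cell division rose almost whole. For S phase and DNA replication, 48 of 49 measured members rose, 0 fell and 1 did not pass (48 and 0 adjusted over the list alone). S phase and DNA replication tested as a list at adjusted p = 4.58e-80, and at adjusted p = 0.0374 with an estimated correlation. Its leading rises were CLSPN (3.67) and CDC45 (3.74). For G2/M and mitosis, 54 members rose, 0 fell and 0 of 54 did not pass (54 and 0 adjusted over the list alone). G2/M and mitosis tested as a list at adjusted p = 9.28e-122, and at adjusted p = 0.125 with an estimated correlation. Beside MKI67, CDCA8 and CDCA2 (4.02) led it. For ribosome biogenesis and MYC targets, of 38 members 37 rose, 0 fell and 1 did not pass (37 and 0 adjusted over the list alone), led by NOP56 (1.38) and the spermidine synthase SRM (1.38), while MYC itself was at 0.01 (SE 0.091, adjusted p = 0.916). Ribosome biogenesis and MYC targets tested as a list at adjusted p = 3.35e-14, and at adjusted p = 0.374 with an estimated correlation. Cytoplasmic ribosomal proteins went the other way and by less, since 2 of 47 measured members rose, 27 fell and 18 did not pass (2 and 27 adjusted over the list alone), with RPL15 at -0.80 and RPL37 at -0.73. Cytoplasmic ribosomal proteins tested as a list at adjusted p = 0.0178, and at adjusted p = 0.647 with an estimated correlation. CCND1, the cyclin of G1, rose by 0.88 (SE 0.213, adjusted p = 0.00791). In the list of G1 and immediate early genes, 11 of 33 rose and 10 fell (11 and 11 adjusted over the list alone), with DUSP1 (2.07) and ETV5 (1.15) higher and EGR2 and EGR3 lower.

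Most listed genes of quiescence and of growth arrest fell. For FOXO targets and quiescence, 1 member rose, 24 fell and 4 of 29 did not pass (1 and 24 adjusted over the list alone), among them the ubiquitin ligase FBXO32 (-4.35), SESN1 (-1.55) and HBP1 (-1.56). FOXO targets and quiescence tested as a list at adjusted p = 1.35e-09, and at adjusted p = 0.374 with an estimated correlation. For p53 targets, of 30 members 2 rose, 26 fell and 2 did not pass (3 and 26 adjusted over the list alone), with CDKN1A at -1.10 (SE 0.072, adjusted p = 8.64e-06), CCNG1 at -1.27 and BTG2 at -2.68. The p53 targets tested as a list at adjusted p = 4.17e-09, and at adjusted p = 0.144 with an estimated correlation. For lysosome and autophagy genes, 4 of 31 measured members rose, 21 fell and 6 did not pass (4 and 21 adjusted over the list alone), with WIPI1 (-1.92) and the autophagy receptor SQSTM1 (-2.03) lower. Lysosome and autophagy tested as a list at adjusted p = 1.71e-05, and at adjusted p = 0.374 with an estimated correlation.

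Most listed cytoskeletal genes under SRF and MRTF, the actin-sensing factors, rose with serum. In that list 27 members rose, 3 fell and 4 of 34 did not pass (27 and 3 adjusted over the list alone), with ITGA5 (1.47), PDLIM5 (1.46) and ACTN4 (1.49). SRF/MRTF cytoskeletal targets tested as a list at adjusted p = 1.15e-05, and at adjusted p = 0.487 with an estimated correlation. For YAP/TEAD targets, of 24 members 16 rose, 2 fell and 6 did not pass (17 and 2 adjusted over the list alone), with WWC1 (2.06), AXL (1.47) and CCN2, a matricellular growth factor (2.34, SE 0.208, adjusted p = 4.08e-05). YAP/TEAD targets tested as a list at adjusted p = 0.000566, and at adjusted p = 0.487 with an estimated correlation. In the BMP response list 9 of 15 measured members rose, 3 fell and 3 did not pass (9 and 4 adjusted over the list alone), with ID3, GATA2 (1.97) and the antagonist NOG (2.50) higher and MSX2 (-2.31) lower. BMP response tested as a list at adjusted p = 0.0165, and at adjusted p = 0.374 with an estimated correlation. For TGF-beta response genes, 16 of 30 rose and 9 fell (17 and 10 adjusted over the list alone), with SMAD7 at 1.21, TGFB1 at 0.46 and the cell cycle inhibitor CDKN2B at -3.52. Among YAP/TEAD targets 17 rose and 4 fell without PF3 serum-free wells 2 and 3.

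Matrix genes split. Of the collagens and fibrillar matrix genes, 10 of 42 rose and 16 fell (10 and 16 adjusted over the list alone), with the basement membrane collagen COL4A1 (2.42) higher and COL18A1 (-1.52), COL6A1 (-1.52) and LUM (-2.24) lower, and without PF3 serum-free wells 2 and 3 the counts were 11 and 17. COL3A1 fell by 1.25 (SE 0.28, adjusted p = 0.00534), a call that DESeq2 did not make (adjusted p = 0.168) and that was lost without PF2. The fibrillar collagens COL1A1 and COL1A2, FN1 and POSTN were at 0.05, -0.21, -0.11 and -0.15 and did not pass. PF3 FBS wells averaged 5916 CPM of COL1A1, above PF3 serum-free wells 2 and 3 (2596 and 2927) and below well 1 (6714). Its direction in PF3 thus depends on those wells. For collagen processing and crosslinking, 19 members rose, 7 fell and 6 of 32 did not pass (19 and 7 adjusted over the list alone), with P3H2 (2.28), PLOD2 (1.58) and LOX (0.73, SE 0.235, adjusted p = 0.0276) higher. Collagen processing and crosslinking tested as a list at adjusted p = 0.0488, and at adjusted p = 0.536 with an estimated correlation. Among matrix metalloproteinases and inhibitors 9 of 28 rose and 12 fell (9 and 13 adjusted over the list alone), with MMP12 higher and the cathepsin CTSK (-2.13), MMP11 (-2.86) and MMP15 (-1.95) lower.

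Many lipid genes were lower with serum. For cholesterol synthesis and uptake, of 27 members 1 rose, 24 fell and 2 did not pass (1 and 25 adjusted over the list alone), with the regulator SREBF2 (-2.63) and MSMO1 (-3.12) lower. Cholesterol synthesis and uptake tested as a list at adjusted p = 1.91e-11, and at adjusted p = 0.466 with an estimated correlation. For sterol efflux genes under LXR, 0 of 9 measured members rose, 9 fell and 0 did not pass (0 and 9 adjusted over the list alone), with SMPDL3A (-2.58) and the cholesterol pump ABCA1 (-1.28). Sterol efflux (LXR targets) tested as a list at adjusted p = 6.72e-05, and at adjusted p = 0.125 with an estimated correlation. For fatty acid synthesis and desaturation, 0 members rose, 10 fell and 3 of 13 did not pass (0 and 10 adjusted over the list alone), with SCD (-3.72) and FADS2 (-2.24). Fatty acid synthesis and desaturation tested as a list at adjusted p = 1.71e-05, and at adjusted p = 0.487 with an estimated correlation. In the adipogenic and lipofibroblast list of 16 members 1 rose, 13 fell and 2 did not pass (1 and 13 adjusted over the list alone), with ADH1B, FGFR4 (-3.16), FGF10 (-4.28) and the receptor PDGFRA (-1.79, SE 0.08, adjusted p = 1.31e-06). Adipogenic and lipofibroblast genes tested as a list at adjusted p = 2.13e-05, and at adjusted p = 0.125 with an estimated correlation.

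Metabolic and stress lists went both ways. In glycolysis and hypoxia genes 19 of 33 measured members rose, 6 fell and 8 did not pass (20 and 8 adjusted over the list alone), with LDHA (2.11) and ENO1 (1.62) higher and BNIP3L (-1.22) lower. Glycolysis and hypoxia (HIF targets) tested as a list at adjusted p = 0.00274, and at adjusted p = 0.487 with an estimated correlation. For nuclear-encoded oxidative phosphorylation genes, 20 members rose, 5 fell and 10 of 35 did not pass (21 and 7 adjusted over the list alone), with CYCS (1.57). Oxidative phosphorylation (nuclear-encoded) tested as a list at adjusted p = 0.0317, and at adjusted p = 0.642 with an estimated correlation. For mitochondrially encoded transcripts, of 13 members 0 rose, 10 fell and 3 did not pass (0 and 11 adjusted over the list alone), with MT-ND3 (-0.74). Mitochondrially encoded transcripts tested as a list at adjusted p = 0.0381, and at adjusted p = 0.65 with an estimated correlation. Of these, 5 fell without PF3 serum-free wells 2 and 3. In the unfolded protein response 16 of 26 measured members rose, 2 fell and 8 did not pass (16 and 2 adjusted over the list alone), with PDIA4 (1.25) and MANF (0.97). Unfolded protein response of the endoplasmic reticulum tested as a list at adjusted p = 0.00206, and at adjusted p = 0.374 with an estimated correlation. For the cytosolic heat shock response, 12 members rose, 2 fell and 6 of 20 did not pass (12 and 2 adjusted over the list alone), with HSPD1 (1.46) and HSP90AA1 (0.99). Cytosolic heat shock response tested as a list at adjusted p = 0.0174, and at adjusted p = 0.536 with an estimated correlation. For NRF2 targets, of 33 members 3 rose, 24 fell and 6 did not pass (3 and 25 adjusted over the list alone), with AKR1C3 (-2.32), the ferritin FTH1 (-1.92) and HMOX1 (-1.03) lower. Oxidative stress response (NRF2 targets) tested as a list at adjusted p = 5.25e-06, and at adjusted p = 0.374 with an estimated correlation. For other xenobiotic enzymes, 4 of 23 measured members rose, 12 fell and 7 did not pass (4 and 12 adjusted over the list alone), with CYP26B1 (-4.36) and ALDH2 (-1.49). Xenobiotic metabolism (other) tested as a list at adjusted p = 0.000566, and at adjusted p = 0.154 with an estimated correlation. For metallothioneins, 8 members rose, 0 fell and 2 of 10 did not pass (8 and 0 adjusted over the list alone), with MT1X (1.99) and MT1A (2.54). Metallothioneins tested as a list at adjusted p = 0.0305, and at adjusted p = 0.466 with an estimated correlation. For the amino acid response, 9 of 38 rose and 12 fell (7 and 12 adjusted over the list alone), with GDF15 (-2.75) and DDIT3 (-1.22) lower and ASNS at -0.89 (SE 0.385, adjusted p = 0.0768). Of aryl hydrocarbon receptor targets 1 of 13 rose and 8 fell (1 and 8 adjusted over the list alone), with CYP1B1 at -1.70, CYP1A1 at -2.39 and ALDH3A1 at -2.31. Mean levels of ASNS and CYP1A1 lay below 1 CPM in every line and treatment.

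Many inflammatory and immune genes were lower with serum. Of inflammatory cytokines and chemokines, of 35 members 1 rose, 20 fell and 14 did not pass (1 and 20 adjusted over the list alone), with CCL11, CCL2 (-1.68) and the complement component C3 (-2.86). Inflammatory cytokines and chemokines tested as a list at adjusted p = 3.73e-05, and at adjusted p = 0.487 with an estimated correlation. Without PF3 serum-free wells 2 and 3, 2 rose and 21 fell of 33 measured. CXCL8 differed between lines, at 2.26 in N1, 0.11 in PF2 and -2.19 in PF3 (adjusted p for the difference 2.84e-05), and without PF3 serum-free wells 2 and 3 the PF3 value was -0.83 (adjusted p = 0.000579). IL6 was at -0.48 (SE 0.231, adjusted p = 0.104) over the lines. For interferon-stimulated genes, 1 of 40 measured members rose, 22 fell and 17 did not pass (1 and 24 adjusted over the list alone), with PARP14 (-1.86) and STAT2 (-1.65). Interferon-stimulated genes tested as a list at adjusted p = 0.000479, and at adjusted p = 0.472 with an estimated correlation. For complement and antigen presentation, 3 members rose, 18 fell and 1 of 22 did not pass (3 and 18 adjusted over the list alone), with HLA-E (-1.25) and C1S (-1.77). Complement and antigen presentation tested as a list at adjusted p = 0.000204, and at adjusted p = 0.339 with an estimated correlation. In the prostaglandin list 3 of 16 rose and 10 fell (3 and 10 adjusted over the list alone), with PTGS1 (1.48) higher and PTGDS (-2.51) lower.

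In signalling lists, growth-factor ligands and receptors went both ways: 13 of 37 rose and 15 fell (13 and 16 adjusted over the list alone), with MET (2.61) and FGF5 (2.35) higher and PDGFRB (-2.13) lower. Of Hedgehog and WNT genes 7 of 30 rose and 13 fell (7 and 13 adjusted over the list alone), with DKK1 (3.19) higher and PTCH1 (-1.51) lower. Of glucocorticoid receptor targets 5 of 15 rose and 8 fell (5 and 9 adjusted over the list alone), with FKBP5 (1.45) and RGS2 (-1.69). For the circadian clock 8 of 19 rose and 5 fell (8 and 6 adjusted over the list alone), with BMAL2 (1.68) and NFIL3 (-1.11). Of replication-dependent histones 2 of 16 rose and 5 fell (2 and 5 adjusted over the list alone), with H3C8 (2.41) and H4C8 (-1.41), in a family of near-identical genes whose counts are uncertain.

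Markers of other cell types differed in level. In serum-free medium the median over the fibroblast list was 757 CPM, against 12.1 over smooth muscle and pericyte markers, 0.732 over epithelial, 0.328 over mesothelial, 0.281 over endothelial and 0.0187 over leukocyte markers. The highest means were 364 CPM for ACTG2 and 165.4 for KRT7 with FBS, 102.4 for BNC1, a mesothelial marker, with pirfenidone, and 41 for TEK, an endothelial receptor, and 1.25 for LAPTM5, a leukocyte marker, in serum-free medium. For fibroblast markers, of 16 members 1 rose, 11 fell and 4 did not pass (1 and 11 adjusted over the list alone), with SERPINF1 (-1.70) and FBLN1 (-1.90). Fibroblast markers tested as a list at adjusted p = 0.00019, and at adjusted p = 0.466 with an estimated correlation. Of epithelial markers 2 of 12 rose and 2 fell (2 and 1 adjusted over the list alone), with KRT7 and KRT18 (2.03) higher, and without PF3 serum-free wells 2 and 3, of which well 3 carried epithelial transcripts, 5 of 11 rose and 2 fell. N1 FBS well 2 and PF2 FBS well 1 carried such transcripts as well and stayed in these counts. Of smooth muscle and pericyte markers 6 of 13 rose and 2 fell (6 and 2 adjusted over the list alone), with MCAM (3.65) and ACTG2 (3.52) higher and ITGA8 (-2.68) lower. Of mesothelial markers 3 of 7 rose and 1 fell (3 and 1 adjusted over the list alone), with CALB2 (1.77) and PDPN (-2.65). Of endothelial markers 1 of 9 rose and 4 fell (1 and 4 adjusted over the list alone), with VWF (-3.25) and ERG (2.75), and of leukocyte markers 0 of 5 rose and 0 fell (0 and 0 adjusted over the list alone). Mean levels of ERG lay below 1 CPM in every line and treatment, and those of VWF below 1 CPM with FBS. The lists tested past the threshold numbered 27 of 44, and with an estimated correlation 1, the S phase list, with 6 at an unadjusted p under 0.05. For 3 lists that did not pass, immediate early genes, metalloproteinases and growth factors, the mean, the median and the test did not share a sign.

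**Figure D2:**
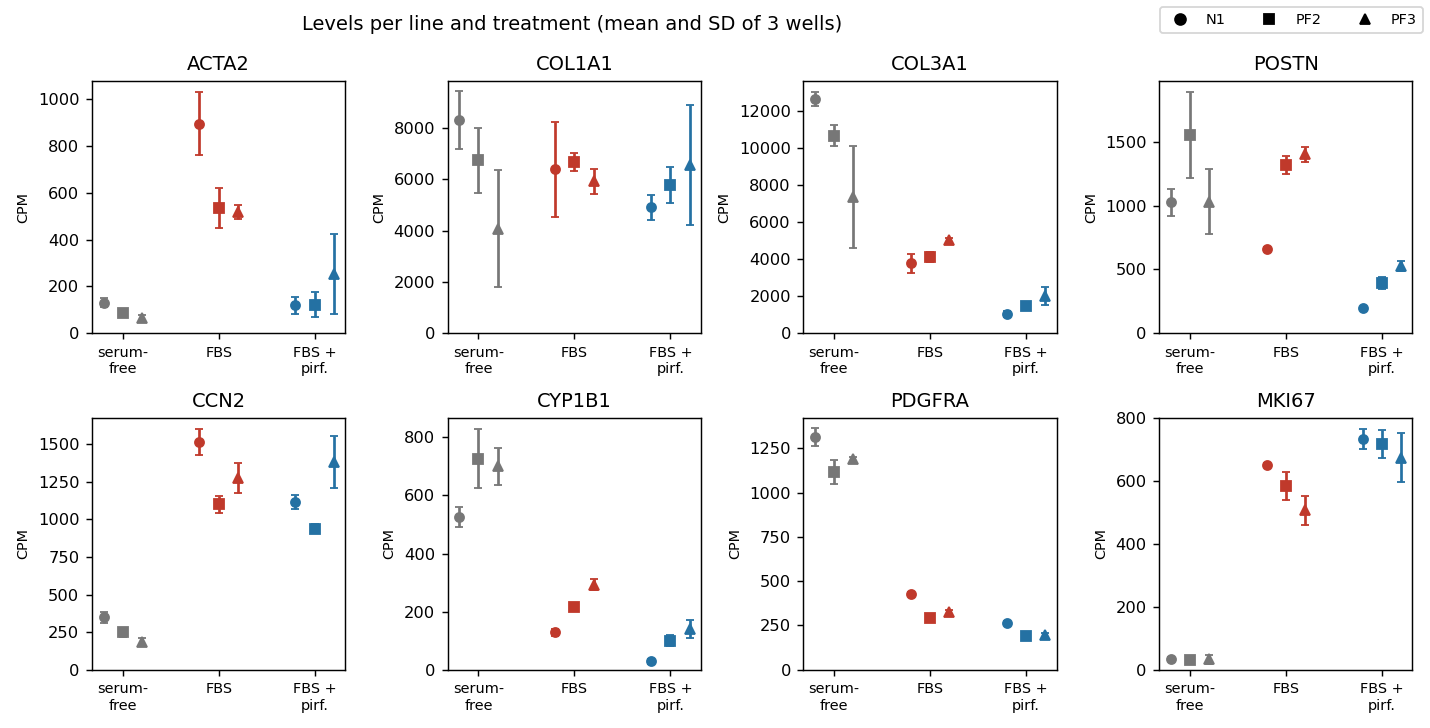
Levels in CPM (vertical axis, from 0) of 8 genes in serum-free medium, FBS, and FBS with pirfenidone, with 1 marker per line giving the mean and SD of 3 wells. ACTA2 went from 92.93 to 649.5 CPM with FBS and was at 164.9 with pirfenidone. COL1A1 averaged between 5745 and 6379 CPM, but its lines went different ways. In serum-free medium, FBS, and FBS with pirfenidone, COL1A1 was at 8321, 6393 and 4910 CPM in N1. It was at 6735, 6664 and 5779 in PF2 and at 4079, 5916 and 6545 in PF3.

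With pirfenidone added to serum, some genes of contractile and matrix proteins, growth factors and chemokines fell, while the S phase and mitosis lists did not pass. ACTA2 went from 649.5 ± 213.4 to 164.9 ± 77 CPM, a change of -1.97 (SE 0.372, adjusted p = 0.0117), with PF3 pirfenidone well 2 at 442.3 CPM above the other pirfenidone wells, which lay between 62.4 and 214.5. TNFRSF11B, the decoy receptor osteoprotegerin (ENSG00000164761, chromosome 8, 118923557 to 118952200), went from 629 ± 96.4 to 72.7 ± 15.7 CPM, by -3.13 (SE 0.131, adjusted p = 6.92e-05). EDNRB, an endothelin receptor (ENSG00000136160, chromosome 13, 77895481 to 77975529), changed by -3.92 (SE 0.332, adjusted p = 0.000694), and EFR3B, a membrane anchor of a lipid kinase (ENSG00000084710, chromosome 2, 25042130 to 25159137), by 2.60 (SE 0.201, adjusted p = 0.000553). Of 19706 genes, 1679 rose and 1838 fell, 153 and 605 of them by at least 2-fold.

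The other large rises were the amino acid transporter SLC6A17 (2.27), the sialomucin PODXL (2.23), the receptor FGFR3 (1.83), the glutamate transporter SLC1A3 (1.75), the selectin ligand SELPLG (1.69), ADAMTSL1 (1.69, SE 0.087, adjusted p = 0.000134), the potassium channel KCNC4 (1.66), SEMA7A (1.65), PCBP3 (1.52), the kinase WNK4 (1.48), the cadherin CELSR1 (1.47), PLPP4 (1.46), PRRG4 (1.44) and TRNP1 (1.43, SE 0.125, adjusted p = 0.000765). The largest fall was ANO3, of the anoctamin family (-5.09, SE 0.554, adjusted p = 0.00155). It was followed by phospholamban, PLN (-4.40, below 1 CPM in PF2 and PF3), the methyltransferase INMT (-4.40), the WNT inhibitor NKD2 (-3.98), the steroid dehydrogenase HSD17B2 (-3.89), BMP5 (-3.78), the chemokine scavenger ACKR4 (-3.66, SE 0.162, adjusted p = 6.92e-05), the orphan receptor NR4A2 (-3.57), B3GALT2 (-3.54), ACTC1 (-3.49), KRT7 (-3.26), RGCC (-3.10, SE 0.182, adjusted p = 0.000229) and the cytokine IL24 (-3.04). All 30 of these genes had the same sign in the 3 lines, which the rule for naming them required. NKD2 and BMP5 lay near the floor as well. In N1, PF2 and PF3, NKD2 was at 1.43, 0.358 and 0.369 CPM with FBS and at 0.03, 0.0667 and 0.0289 with pirfenidone. BMP5 was at 3.67, 0.8 and 0.973 CPM with FBS and at 0.319, 0.0265 and 0.0558 with pirfenidone. The sizes of these falls are thus uncertain.

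**Figure D3:**
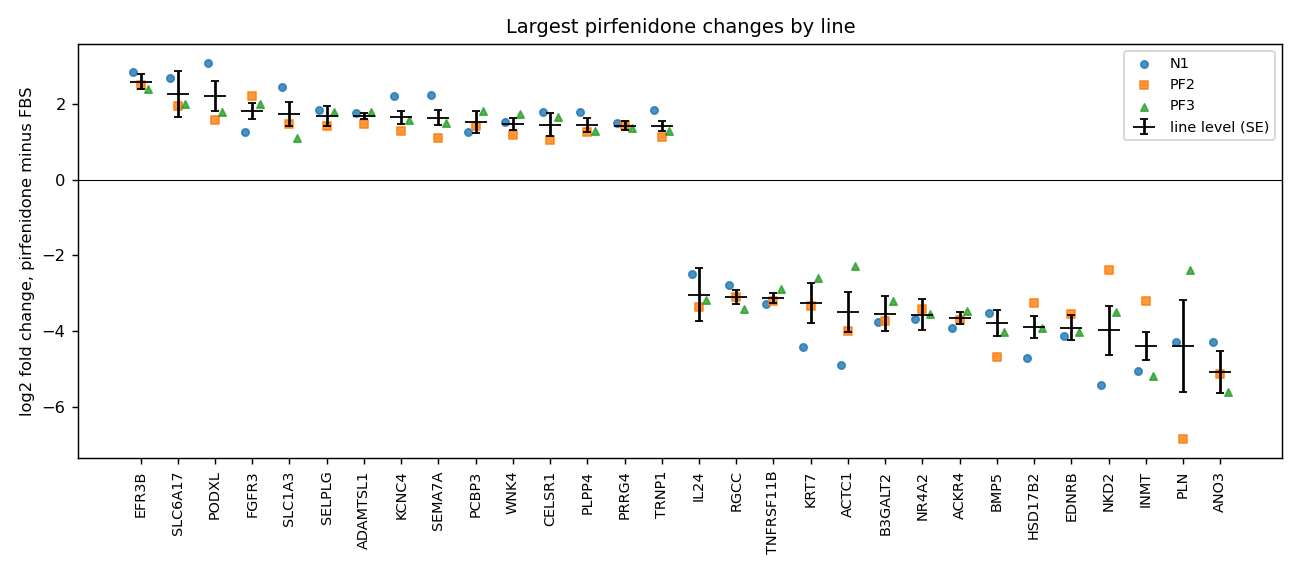
Log2 fold change of FBS with pirfenidone against FBS (vertical axis) for the 15 largest rises and the 15 largest falls, with the line-level value and its SE as a black bar and the values of N1, PF2 and PF3 as markers. EFR3B lies at 2.60 and ANO3 at -5.09, and for genes near 0 CPM with pirfenidone, such as PLN, the size of the fold within a line depends on the prior count.

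Cell division lists did not pass with pirfenidone (adjusted p = 0.219 and adjusted p = 0.966). For S phase and DNA replication 1 of 49 rose and 7 fell (1 and 6 adjusted over the list alone), and for G2/M and mitosis 3 of 54 rose and 4 fell (3 and 3 adjusted over the list alone). MKI67 rose by 0.30 (SE 0.068, adjusted p = 0.024), with PF3 pirfenidone well 2 at 585.2 CPM below the other pirfenidone wells, at 688.5 to 768.9. That call was lost without line PF2, line PF3, PF3 serum-free well 1, PF3 serum-free wells 2 and 3, or the line term. CCNA2 was at -0.41 and MCM2 at -0.38. CDKN1A fell by 0.29 (SE 0.071, adjusted p = 0.029), a call lost without line N1, line PF2, PF3 serum-free well 1, PF3 pirfenidone well 3 or the line term. MYC and CCND1 were at -0.02 and 0.21 and did not pass. Of ribosome biogenesis genes 1 of 38 rose and 0 fell (0 and 0 adjusted over the list alone), and of cytoplasmic ribosomal proteins 0 of 47 rose and 3 fell (0 and 0 adjusted over the list alone). In G1 and immediate early genes 6 of 33 rose and 3 fell (6 and 5 adjusted over the list alone), with EGR1 (1.02) higher and NR4A1 (-1.56) lower. Of FOXO targets 2 of 29 rose and 7 fell (3 and 9 adjusted over the list alone), with KLF2 (1.17) higher and CDKN1C (-2.22) lower, and of p53 targets 1 of 30 rose and 6 fell (4 and 9 adjusted over the list alone), with DDB2 (-0.57). CDKN1C lay near the floor, at 1, 1.06 and 1.35 CPM with FBS in N1, PF2 and PF3 and at 0.371, 0.119 and 0.264 with pirfenidone. With PF3 serum-free wells 2 and 3 left out, 1 S phase gene rose and 11 fell, 7 G1 and immediate early genes rose and 7 fell, 3 p53 targets rose and 9 fell, and 5 cytoplasmic ribosomal proteins fell.

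Growth factors were the list with the lowest p. Among growth-factor ligands and receptors 2 of 37 measured members rose, 16 fell and 19 did not pass (2 and 19 adjusted over the list alone), with HGF (-2.14, SE 0.133, adjusted p = 0.000279), FGF7 (-1.60, SE 0.109, adjusted p = 0.000328), BDNF (-2.22, SE 0.162, adjusted p = 0.000457) and the activin antagonist FST (-1.33, SE 0.113, adjusted p = 0.000694) lower. Growth-factor ligands and receptors tested as a list at adjusted p = 3.25e-11, and at adjusted p = 0.0815 with an estimated correlation. PDGFRA changed by -0.68 (SE 0.078, adjusted p = 0.00191), and PDGFRB was at -0.56 (SE 0.218, adjusted p = 0.122). In the adipogenic and lipofibroblast list 1 member rose, 8 fell and 7 of 16 did not pass (1 and 9 adjusted over the list alone), with the mesenchymal factor TCF21 (-2.17, SE 0.138, adjusted p = 0.000304), ZFP36L2 (-1.06) and the scavenger receptor CD36 (-1.85) lower. Adipogenic and lipofibroblast genes tested as a list at adjusted p = 2.16e-07, and at adjusted p = 0.0815 with an estimated correlation. Of Hedgehog and WNT genes, of 30 members 3 rose, 13 fell and 14 did not pass (3 and 14 adjusted over the list alone), with WNT5A (-1.36), DKK1 (-1.39), DKK2 (-1.58) and RSPO3 (-2.40) lower. Hedgehog and WNT signalling tested as a list at adjusted p = 0.000359, and at adjusted p = 0.297 with an estimated correlation.

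Of the collagens and fibrillar matrix genes, 1 of 42 measured members rose, 16 fell and 25 did not pass (1 and 19 adjusted over the list alone). Collagens and fibrillar matrix tested as a list at adjusted p = 1.37e-08, and at adjusted p = 0.554 with an estimated correlation. Tenascin TNC (-1.48, SE 0.124, adjusted p = 0.000694), FAP (-0.74), COL8A1 (-1.68) and COL16A1 (-0.92) led the falls, and COL3A1 (-1.54, SE 0.28, adjusted p = 0.0103) and POSTN, periostin (-1.62, SE 0.23, adjusted p = 0.00416), fell too. The main fibrillar collagens did not pass, with COL1A1 at -0.15 (SE 0.229, adjusted p = 0.707) and COL1A2 at -0.28 (SE 0.215, adjusted p = 0.417), nor did FN1 (-0.07), LOX (-0.19), CCN2 (-0.17) or ELN (-2.24, SE 0.713, adjusted p = 0.0683). COL1A1 went from 6393 to 4910 CPM in N1, from 6664 to 5779 in PF2 and from 5916 to 6545 in PF3. The SD over the 3 PF3 wells with pirfenidone was 2340. For collagen processing 5 of 32 rose and 6 fell (6 and 10 adjusted over the list alone), with LOXL1 (0.88) and P4HA2 (0.60) higher and P4HA1 (-0.67) lower. Of metalloproteinases and inhibitors 4 of 28 rose and 5 fell (4 and 6 adjusted over the list alone), with the aggrecanase ADAMTS5 (-2.25, SE 0.106, adjusted p = 7.47e-05) and ADAMTS1 (-1.43) lower and MMP15 (1.24) and TIMP1 (0.69) higher. Without PF3 serum-free wells 2 and 3, which enter this comparison through the shared spread, 2 collagen and matrix genes rose and 22 fell, 6 collagen processing genes rose and 11 fell, and 4 metalloproteinases and inhibitors rose and 8 fell.

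In the SRF/MRTF list 0 members rose, 9 fell and 25 of 34 did not pass (0 and 12 adjusted over the list alone), with ITGA5 (-0.58), ACTG2 (-1.66) and MYLK (-0.80), which serum also lowered (-0.43). SRF/MRTF cytoskeletal targets tested as a list at adjusted p = 0.000381, and at adjusted p = 0.674 with an estimated correlation. For smooth muscle and pericyte markers, of 13 members 0 rose, 6 fell and 7 did not pass (1 and 6 adjusted over the list alone), with KCNJ8 (-0.54), SYNPO2 (-1.86) and MCAM (-0.81). Smooth muscle and pericyte markers tested as a list at adjusted p = 0.00507, and at adjusted p = 0.554 with an estimated correlation. Of TGF-beta response genes 8 of 30 rose and 4 fell (8 and 5 adjusted over the list alone). TGFB1 rose by 0.44 (SE 0.052, adjusted p = 0.00211) and SMAD7 by 0.47, and WNT5A fell. Of YAP/TEAD targets 2 of 24 rose and 4 fell (2 and 4 adjusted over the list alone), with the coagulation factor receptor F3 (-1.70) lower, and of BMP response genes 0 of 15 rose and 3 fell (0 and 3 adjusted over the list alone), with NOG (-1.48) and GREM1 (-0.78) lower. Among SRF/MRTF targets 1 rose and 13 fell, and among BMP response genes 0 rose and 5 fell, without PF3 serum-free wells 2 and 3.

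Of inflammatory cytokines and chemokines, 0 of 35 measured members rose, 7 fell and 28 did not pass (0 and 10 adjusted over the list alone), with the monocyte chemokine CCL2 (-2.72, SE 0.097, adjusted p = 6.92e-05), CXCL12 (-1.95, SE 0.229, adjusted p = 0.00207), TSLP (-0.82) and ICAM1 (-1.07). Inflammatory cytokines and chemokines tested as a list at adjusted p = 3.98e-05, and at adjusted p = 0.619 with an estimated correlation. Of 33 measured, 13 fell without PF3 serum-free wells 2 and 3. CXCL8 was at -1.36 (SE 0.897, adjusted p = 0.342) and IL6 at -0.12 (SE 0.232, adjusted p = 0.765), neither passing, and CXCL8 in N1 pirfenidone well 3 was at 48.34 CPM against 5.37 to 26.31 in the other pirfenidone wells. In the prostaglandin list 0 of 16 rose and 4 fell (2 and 6 adjusted over the list alone), with PTGES (-1.35). Of interferon-stimulated genes 0 of 40 rose and 8 fell (0 and 9 adjusted over the list alone), with EPSTI1 (-1.73) and IFI44L (-2.38) lower, and 10 of 39 members measured per well differed between lines (20 adjusted over the list alone). Of complement and antigen presentation genes 0 of 22 rose and 3 fell (0 and 3 adjusted over the list alone). Of glucocorticoid receptor targets 2 members rose, 7 fell and 6 of 15 did not pass (2 and 8 adjusted over the list alone), with CRISPLD2 (-1.47, SE 0.124, adjusted p = 0.000694), MAOA (-0.93) and RGS2 (-0.99) lower. FKBP5 went the other way in N1, PF2 and PF3, from 35.5, 35.95 and 33.4 CPM with FBS to 56.9, 48.4 and 50.4 with pirfenidone. Glucocorticoid receptor targets tested as a list at adjusted p = 0.000308, and at adjusted p = 0.189 with an estimated correlation. For the circadian clock 3 of 19 rose and 5 fell (5 and 6 adjusted over the list alone), with BMAL1 (-0.97, SE 0.065, adjusted p = 0.000328), NFIL3 (-0.81) and PER3 (-0.64) lower and BHLHE40 (0.76) higher. With PF3 serum-free wells 2 and 3 left out, 2 prostaglandin genes rose and 5 fell, 2 interferon-stimulated genes rose and 10 fell, and 5 clock genes rose and 6 fell.

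In glycolysis and hypoxia genes of 33 members 2 rose, 13 fell and 18 did not pass (2 and 13 adjusted over the list alone), with the carbonic anhydrase CA9 (-2.59), PDK1 (-0.70) and ADM (-1.78) lower. CA9 lay near the floor, at 0.907, 1.188 and 1.055 CPM with FBS in N1, PF2 and PF3 and at 0.0993, 0.277 and 0.15 with pirfenidone. Glycolysis and hypoxia (HIF targets) tested as a list at adjusted p = 0.000292, and at adjusted p = 0.554 with an estimated correlation. For aryl hydrocarbon receptor targets, 0 of 13 measured members rose, 6 fell and 7 did not pass (0 and 7 adjusted over the list alone), with HSPB2 (-1.68), the repressor AHRR (-0.79) and CYP1B1 (-1.38, SE 0.299, adjusted p = 0.0184) lower and CYP1A1 at 0.74 (SE 0.552, adjusted p = 0.398). Aryl hydrocarbon receptor targets tested as a list at adjusted p = 0.000102, and at adjusted p = 0.415 with an estimated correlation. Of other xenobiotic genes 1 of 23 rose and 3 fell (1 and 4 adjusted over the list alone), with the drug pump ABCB1 (1.19, SE 0.098, adjusted p = 0.000664) higher and CYP26B1 (-1.55) lower, and without PF3 serum-free wells 2 and 3, 1 rose and 8 fell. Mean levels of CYP26B1 lay below 1 CPM with FBS and with pirfenidone. For the cytosolic heat shock response, 8 members rose, 0 fell and 12 of 20 did not pass (13 and 1 adjusted over the list alone), with HSP90AA1 (0.67), HSPB8 (0.60) and DNAJB1 (0.48). Cytosolic heat shock response tested as a list at adjusted p = 6.04e-05, and at adjusted p = 0.554 with an estimated correlation. For mitochondrially encoded transcripts, of 13 members 2 rose, 0 fell and 11 did not pass (4 and 0 adjusted over the list alone), with MT-ND6 (0.44) and MT-ND4L (0.40), and 0 rose without PF3 serum-free wells 2 and 3 (edgeR). Mitochondrially encoded transcripts tested as a list at adjusted p = 0.00687, and at adjusted p = 0.692 with an estimated correlation.

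Other metabolic and stress lists did not pass. For cholesterol synthesis 2 of 27 rose and 0 fell (0 and 0 adjusted over the list alone). Of LXR targets 0 of 9 rose and 2 fell (0 and 2 adjusted over the list alone), with NR1H3 (-0.78) and ABCA1 (-0.59), and of fatty acid genes 1 of 13 rose and 0 fell (1 and 0 adjusted over the list alone), with ACACA (0.45). For nuclear-encoded oxidative phosphorylation 0 of 35 rose and 2 fell (0 and 0 adjusted over the list alone), for the amino acid response 0 of 38 rose and 2 fell (0 and 2 adjusted over the list alone), and for the unfolded protein response 3 of 26 rose and 1 fell (3 and 1 adjusted over the list alone). For NRF2 targets 4 of 33 rose and 5 fell (4 and 5 adjusted over the list alone), with PIR (-0.78) lower, TXNRD1 (0.39) higher and HMOX1 at 0.47 (SE 0.224, adjusted p = 0.194). Of lysosome genes 6 of 31 rose and 2 fell (6 and 2 adjusted over the list alone), of metallothioneins 1 of 10 rose and 1 fell (1 and 1 adjusted over the list alone), and of histones 1 of 16 rose and 3 fell (1 and 3 adjusted over the list alone). Of 39 amino acid response genes 1 rose and 6 fell, and of fatty acid genes 4 rose and 0 fell, without PF3 serum-free wells 2 and 3.

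For fibroblast markers, 0 of 16 measured members rose, 5 fell and 11 did not pass (0 and 5 adjusted over the list alone), with TCF21, FAP and S100A4 (-0.83). Fibroblast markers tested as a list at adjusted p = 4.17e-05, and at adjusted p = 0.554 with an estimated correlation. For epithelial markers, 0 members rose, 3 fell and 9 of 12 did not pass (0 and 3 adjusted over the list alone). Epithelial markers tested as a list at adjusted p = 0.00888, and at adjusted p = 0.662 with an estimated correlation. The 3 were KRT7, MUC1 (-1.09) and KRT19 (-0.93), keratins and a mucin found in these wells at a highest mean of 165.4 CPM with FBS. N1 FBS well 2, PF2 FBS well 1 and PF3 pirfenidone well 2 held traces of other epithelial transcripts. Single wells were left out in turn, but how far these wells together shape the falls was not tested. Of endothelial markers 1 of 9 rose and 2 fell (2 and 2 adjusted over the list alone), with ERG (1.60) higher and TEK (-0.87) and KDR (-1.07) lower, of mesothelial markers 1 of 7 rose and 1 fell (1 and 3 adjusted over the list alone), and of leukocyte markers 0 of 5 rose and 0 fell (0 and 0 adjusted over the list alone). Mean levels of ERG lay below 1 CPM with FBS and with pirfenidone, and those of KDR below 1 CPM with pirfenidone. In all, 14 of 44 lists passed with the preset correlation and 0 with an estimated one (camera, 5 at an unadjusted p under 0.05). For 8 of the lists that did not pass, interferon-stimulated genes and TGF-beta response among them, the mean, the median and the test did not share a sign.

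Among genes named, 135 lost their pirfenidone call without line PF2, ACTA2, COL3A1, POSTN, PDGFRA and TGFB1 among them, and COL3A1 also with DESeq2 (adjusted p = 0.126). Without line PF2, 37 genes rose and 166 fell, without N1 735 and 1020, and with PF2 and PF3 summed as 1 line, chosen after the data were seen, 474 and 749, while a fit without the line term gave 990 and 1113 and the 27 wells as replicates 3547 and 3674. Within single lines, pirfenidone changed 5152 genes in N1, 4151 in PF2 and 4209 in PF3 of 17985 tested, and serum 11501, 11460 and 10887.

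**Figure D4:**
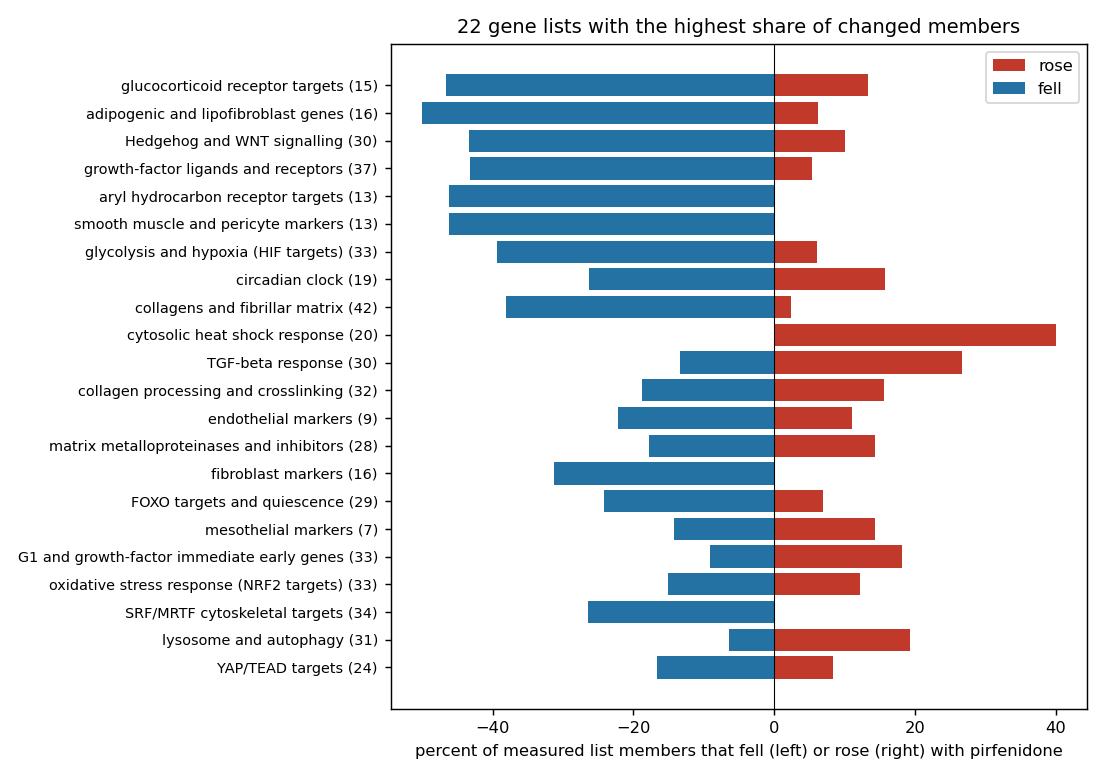
Percent of measured members that rose (right, red) or fell (left, blue) with pirfenidone, from 0 in the middle, for the 22 lists with the highest share of changed members and with the number measured in brackets. In the growth-factor list 16 of 37 fell and 2 rose, and in the heat shock list 8 of 20 rose.

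Wells with serum and pirfenidone were compared with serum-free wells to see how much of the serum response was present with the drug. Of 19706 genes 6224 were higher and 6598 lower. The S phase list was higher in 48 of 49 members and the G2/M list in 54 of 54, with MKI67 at 4.42 (SE 0.079, adjusted p = 1.02e-07). ACTA2 did not pass against the serum-free level, at 0.85 (SE 0.366, adjusted p = 0.072). CCN2 lay 2.17 above it, with COL3A1 at -2.80, POSTN at -1.77, PDGFRA at -2.47 and CYP1B1 at -3.08. Of inflammatory genes of 35 members 2 rose, 25 fell and 8 did not pass (2 and 26 adjusted over the list alone). Inflammatory cytokines and chemokines tested as a list at adjusted p = 2.58e-07, and at adjusted p = 0.392 with an estimated correlation. Of fibroblast markers, 1 of 16 measured members rose, 11 fell and 4 did not pass (1 and 11 adjusted over the list alone), and for collagens and fibrillar matrix 5 members rose, 22 fell and 15 of 42 did not pass (5 and 22 adjusted over the list alone). Fibroblast markers tested as a list at adjusted p = 1.02e-06, and at adjusted p = 0.372 with an estimated correlation. Collagens and fibrillar matrix tested as a list at adjusted p = 0.000969, and at adjusted p = 0.564 with an estimated correlation. Of 44 lists 26 passed, and 0 with an estimated correlation (camera, 6 at an unadjusted p under 0.05).

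Across 17985 genes the pirfenidone effect had little linear relation to the serum effect. With FBS wells split between the effects, the slope of the pirfenidone effect on the serum effect had a median of 0.0171 over 54 choices (from -0.0034 to 0.0365), with a covariance of 0.0179, Pearson's r of 0.0369 and Spearman's rho of 0.0658, all across genes, which are not independent replicates. With the same wells in both effects the slope was 0.0047 and the covariance 0.0049. Simulated unchanged groups gave a covariance of -0.0107. Their slope of -0.516 is no baseline for the real slope, since without a serum effect it is divided by the spread of noise alone. In 6 refits with FBS wells split between the effects, genes that rose with both numbered 680 to 940, where independent lists would share 474.2 to 635.6, and those that fell with both 776 to 867 against 564.7 to 639.6. Genes that rose with serum and fell with pirfenidone, as ACTA2 and KRT7 did over all wells, numbered 599 to 663 against 550.4 to 624.2. In each of the 6 refits they were more than independent lists would share. Those that fell with serum and rose with pirfenidone numbered 507 to 651 against 486.6 to 651.3, and in 1 refit 643 against 651.3. The numbers for independent lists take no account of how easily a gene is called, so an excess need not reflect a shared response.

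The lines differed in how far genes responded. The pirfenidone effect differed between lines for 107 of 17985 genes, and 2402 genes were called in the same direction in all 3 lines. HAS2, the hyaluronan synthase (ENSG00000170961, chromosome 8, 121612116 to 121641390), changed by -0.55 in N1, -2.38 in PF2 and -1.93 in PF3 (adjusted p = 6.69e-05). Interferon-stimulated genes, which respond to viral RNA and interferon, included 4 of the 10 genes with the smallest p. IFIT2 (ENSG00000119922, chromosome 10, 89283694 to 89309276) went there from 5.03 ± 1.39 to 102.7 ± 25.7 CPM (SD, n = 3 wells), a change of 4.37 against 1.04 in PF2 and 0.18 in PF3 (edgeR adjusted p = 0.000339 for the difference), and IFIT3, IFI44 and DDX60 changed by 2.38, 2.13 and 1.41 in N1. CHST11, a chondroitin sulfotransferase, was at 2.39, 0.78 and 0.90, and HMOX1, the heme oxygenase, at 1.21, 0.24 and -0.08 in N1, PF2 and PF3. N1 pirfenidone well 1 had 82.7 CPM of HMOX1 against 109.3 to 134.6 in the other pirfenidone wells. FAM180A and RGS4 changed by 0.54 and 0.73 in N1 against -0.56 and -0.42 in PF2. MYH11, the smooth muscle myosin, changed by -3.94 in N1, from 14.6 to 0.954 CPM, and lay below 0.3 CPM in PF2 and PF3 with FBS and with pirfenidone. Contrasts of N1 with the mean of PF2 and PF3 called 201 genes, and PF2 against PF3 called 4.

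The count of 107 fell to 32 without N1 pirfenidone well 3 and rose to 245 without PF3 pirfenidone well 3. The serum effect differed between lines for 2029 genes, with ELN at 3.78, 5.28 and 6.78 in N1, PF2 and PF3 (adjusted p = 0.00167). Without PF3 serum-free wells 2 and 3 the PF3 value of ELN was 5.68 (adjusted p = 0.0273 for the difference). Without PF3 serum-free wells 2 and 3, left out after the data were seen, 608 genes differed.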

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

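Tests chosen after the result was seen were those of epithelial RNA and library depth, and the other splits and permutations. The test that leaves out single N1 wells was written before.

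Wells far from the other 8 of their treatment were looked for in 87 groups, of which 6 held one, and chance alone gives about 1 in 20. Total count was 40.64 M reads in N1 serum-free well 1, against 20.9 to 29.62 in the other serum-free wells. The protein-coding percent of counts was 98.28 in PF3 pirfenidone well 3, against 98.32 to 98.36. PF3 pirfenidone well 2 had ACTA2 at 442.3 CPM, against 62.4 to 214.5, and MKI67 at 585.2 CPM, against 688.5 to 768.9. CXCL8 was at 48.34 CPM in N1 pirfenidone well 3, against 5.37 to 26.31, and HMOX1 at 82.7 CPM in N1 pirfenidone well 1, against 109.3 to 134.6.

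Effects that differed between lines were found with a test of the difference itself. The serum effect differed for 2029 genes. Residuals of a fit without line differences were permuted (limma on log2 CPM). Of 100 orders 1, the real one, gave as many, with 1551 genes against at most 80 in the others. The count thus exceeded what the spread between wells gave. The orders permute wells, which may be repeat preparations of 1 culture, so chance differences between cultures are not excluded. Leaving out 1 well gave 1321 to 3064 genes (edgeR). The pirfenidone effect differed for 107 genes. There too 1 of 100 orders, the real one, gave as many, with 286 genes against at most 213 in the others, so the margin was small. This limma test is not the edgeR test that gave 107 genes. It too permutes wells, so chance is not excluded for the count. Adjusted p-values of the pirfenidone difference were 6.69e-05 for HAS2, 0.00026 for IFIT3, 0.000339 for CHST11 and IFIT2, 0.00037 for FAM180A, RGS4, IFI44, DDX60 and HMOX1, and 0.000384 for MYH11 (edgeR).

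IFIT3, IFIT2, IFI44 and DDX60 rose with pirfenidone in N1 and had another effect in PF2 and PF3, with IFIT3 at 2.38, 0.16 and -0.29. A single aberrant N1 well is argued against, since leaving out any 1 of the 6 N1 wells with serum left IFIT3, IFIT2, IFI44 and DDX60 with adjusted p of at most 0.00385. Of 39 list members measured, 28 had a higher effect in N1 than in the mean of PF2 and PF3, with medians of 0.501, 0.01 and -0.321 in N1, PF2 and PF3. A difference between the lines, in disease state or otherwise, may underlie this, but with 1 normal line that hypothesis was not tested, and an event shared by the N1 wells with pirfenidone stays open.

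PF3 serum-free wells 2 and 3 differed from well 1, with CXCL8 at 434.5 and 250.8 against 102.3 CPM and DCN at 1882 and 2827 against 7716, genes chosen after their values were seen. RNA from epithelial cells is argued against for well 2, where epithelial genes below 1 CPM in well 1 reached at most 0.892 CPM, and for the 63 of 75 genes 2-fold apart in well 3 that were 2-fold apart the same way in well 2. It stays open only for the other 12, as epithelial genes reached 15.5 CPM in well 3, although all 75 moved the same way in well 2. Library depth is argued against for both, since totals were 23.4, 23.2 and 25.6 M reads and 187 and 75 genes lay 2-fold apart from well 1, against at most 30 and 11 in pairs of the other lines with a larger ratio of totals, a test added after thinning to 20.88 M reads, which left 189 and 73 against at most 32, had not decided for well 3. A difference in the state of these cultures could remain, and no biological explanation was tested, as the labels name none.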

How the results depend on the processing

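Chosen after the data were seen were PF2 and PF3 summed as 1 line, PF3 serum-free wells 2 and 3 left out, and lists tested over 27 wells with an estimated correlation. Under no alternative did a result change direction past the threshold, and the causes of other changes were not tested. Genes higher and lower with pirfenidone (1679 and 1838) numbered 3547 and 3674 with 27 wells as replicates, 990 and 1113 without the line term, 2894 and 3070 with only the 2 treatments compared, and 474 and 749 with PF2 and PF3 summed, of which 473 and 739 were shared. DESeq2 gave 2776 higher. Leaving out 1 line, they were 37 and 166 without PF2, 735 and 1020 without N1, and 1267 and 1669 without PF3. Each of these fits left out 1 line, so sample number alone does not account for the low counts without PF2. Leaving out 1 well gave 1365 to 1879 higher and 1495 to 2020 lower. Genes lower with serum (6145) numbered 4011 without PF2 and 5718 without PF3, and 5841 to 6214 without 1 well.

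The 2029 genes whose serum effect differed between lines became 608 without PF3 serum-free wells 2 and 3, 1321 without PF3 serum-free well 2 and 3064 without PF3 serum-free well 1. The 107 of pirfenidone became 711 with no filter, 601 with DESeq2 and 215 without PF3 serum-free wells 2 and 3. Leaving out 1 well, they were 32, 45 and 177 without N1 pirfenidone wells 3, 2 and 1, 64 without N1 FBS well 2, 71 without PF3 FBS well 2, 68 and 245 without PF3 pirfenidone wells 1 and 3, and 205 without PF3 serum-free well 1. Gene lists past the threshold (27 for serum, 14 for pirfenidone, 26 for pirfenidone against serum-free) fell to 1, 0 and 0 with an estimated correlation, and with 27 wells as well, tried after that, to 7, 4 and 7. The slope of the effects was 0.0047 with the same FBS wells in both. Counts within single lines and of pirfenidone against serum-free stayed within 1.5 times in each alternative that was run.

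Of named genes, the pirfenidone call was lost for 135 without PF2, 30 without N1, 14 without PF3, 48 without the line term and 51 with PF2 and PF3 summed. Over all single wells left out, 91 such calls were lost. ACTA2, POSTN, PDGFRA and TGFB1 lost it only without PF2, among the alternatives run, and EDNRB, TNFRSF11B, EFR3B, CCL2 and HGF in none. Depth limits calls among genes with low counts, which the filter left out.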

Other observations

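Tests chosen after the result was seen were those of the slope bound and of the other splits.

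CEACAM5, CEACAM6 and AGR2, epithelial genes chosen after their values were seen, reached 1 CPM in 4 of 27 libraries, and the highest value in the other 23 was 0.753 CPM. In order, they were at 2.48, 9.5 and 0.863 CPM in N1 FBS well 2, 7.32, 23.5 and 18.2 in PF2 FBS well 1, 7.5, 3.01 and 0.919 in PF3 serum-free well 3, and 1.04, 0.303 and 3.12 in PF3 pirfenidone well 2. Between lines given FBS, 223 genes lay at least 4-fold apart between N1 and PF2 with adjusted p under 0.05 by edgeR, 237 between N1 and PF3, and 0 between PF2 and PF3, where 249 passed at any size. In serum-free medium these were 251, 470 and 54, with 1347 genes at any size between PF2 and PF3, and with pirfenidone 237, 287 and 3. Genes at least 4-fold apart in each of the 3 treatments numbered 71 between N1 and PF2, 84 between N1 and PF3, and 0 between PF2 and PF3. Whether PF2 and PF3 come from 1 donor was not tested. If they do, the n = 3 lines used here holds fewer donors, which the counts with PF2 and PF3 summed as 1 line allow for.

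A hypothesis of a general weakening of the serum response by pirfenidone was tested on the slope between the effects, which it would take below -0.1. The lowest of the 54 slopes was -0.0034, so this explanation is unlikely across genes, although single genes such as ACTA2 rose with serum and fell with pirfenidone. That slope shares its libraries with the comparisons themselves, so it was found and tested on the same data.

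Other splits of the samples were counted for the comparisons of 3 against 3, where 10 splits exist and are too few for a share under 0.05. In each, 1 split, the real one, gave as many genes. The real values were 12016 genes for serum, 3517 for pirfenidone and 12822 for pirfenidone against serum-free over the lines, 11501, 11460 and 10887 for serum within N1, PF2 and PF3, and 5152, 4151 and 4209 for pirfenidone. The highest other split gave 0 for each (edgeR). Every other split puts libraries of both treatments into each group, so any treatment effect enters the spread. These counts of 0 are therefore no support for the real ones.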
